A study of Equus caballus with 25 samples.

How the data were processed

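Messenger RNA of 25 endometrial biopsies was measured on one-colour Agilent arrays, with 5 mares at each of days 0, 3, 8, 12 and 16 of the cycle. Per the labels' protocols, RNA was extracted with Trizol and labelled with Cy3. The deposited values are intensities: per the file headers, Agilent Feature Extraction 10.7.3.1 subtracted the background and removed spatial trends within each array. No normalization between arrays is recorded. The deposited table of values equalled the processed signal of the scanner output in all 25 arrays. The labels state no model or test.

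From these intensities, log2 values were computed and the 75th percentile of each array was subtracted. Spots that the scanner software marked as outliers were set to missing, and spots of the same probe were averaged. A probe was tested where it was well above background on at least 4 of the 5 arrays of some day, which left 35770 of 43603 probes. This processing assumes that the 75th percentile does not itself change with the day, and a change in total RNA would not be seen.

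Differences were tested with limma 3.58.1 in R 4.3.3. All 25 arrays were in 1 model with the day as its term, with moderated tests and Benjamini-Hochberg adjustment within each comparison, and an adjusted p under 0.05 was called a change. The comparisons were the successive days, day 0 against day 16, day 8 against day 0 and the F test over the 5 days. All tests are two-sided. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 17 lists and 6 comparisons together, and repeated with an estimated correlation. Of the 102 list tests 2 passed, of which 0 passed with an estimated correlation, where 6 had an unadjusted p under 0.05. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

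Gene names came from a table of RefSeq genes on the assembly TB-T2T, matched by accession. Symbols were found for 1307 probes of 620 genes. The 32565 probes named by Ensembl transcripts, 6468 named by GenBank or EST accessions and 1724 named only by a probe identifier were not matched to a symbol. Each list was therefore tested only on members with a named and tested probe. These were 5 of 42 for extracellular matrix, 9 of 35 for uterine secretory proteins and 10 of 44 for interferon-stimulated genes. For matrix proteases and their inhibitors they were 6 of 41. The arrays predate that assembly, so no genome positions are given. Each gene was represented by its probe with the highest mean signal, and symbols made of LOC and a number were treated as identifiers, a rule added after the design was fixed. Per comparison, the genes named were those that passed the test in the same direction in all 5 mares, up to 10 largest rises and 10 largest falls, with up to 4 called members of each list described, and the hormone response genes always. Values of some genes that met this rule are not reported here. The comparisons, tests, lists, naming rule and most alternatives were fixed before the data were examined.

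A gene that was at background on all arrays of a day is given a lower bound of its fold. The bound was computed against the lowest signal of any probe well above background on the same array. It was computed for the main background correction only. Close paralogues, such as the CYP3A and kallikrein genes and beta-lactoglobulin, are uncertain, since cross-hybridization was not tested.

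The labels give the same mare to arrays with the same number. Deviations from the day means had a median correlation of 0.245 between arrays of the same mare and of −0.047 between arrays of different mares. Among 26 pairs of the same mare on different slides it was 0.120, so the 0.245 mixes mare and slide in part. The mare was tried as a block. The arrays lay on 7 slides of 3 or 4 arrays and were scanned on 4 days. Within each slide that held both days of a comparison, the direction of the called probes was compared with the pooled one, and for day 0 against day 16 also that of probes called without the slide. The alternatives were quantile normalization, normexp background correction, no filter or a stricter filter on dim probes, mare, slide or both as blocks, only the 2 days compared, an intensity trend in the moderation, a 2-fold minimum, 1 probe per target, and leaving out each array or mare. Chosen after seeing the data were normexp with marked local backgrounds replaced on all arrays or on the day 8 array of mare 2 alone, where the planned normexp broke down (local backgrounds up to 772899), the signal level of each array as a covariate, and leaving out the 2 arrays that stand apart.

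Normexp used the median signal of each spot, since the output holds no mean signal. An offset of 50 was added to each corrected signal before scaling. By construction it lowers the log2 changes of dim probes and weighs more on dimmer arrays, such as those of day 0. The normexp variants therefore do not test background correction alone. Values taken from the deposited table were identical to those analysed and gave no separate test.

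The procedure was tested on simulated data made for day 3 against day 0 with 35770 probes. It recovered 2 of 67 probes changed by a log2 of 0.5, 24 of 67 changed by 1 and 52 of 66 changed by 2, with 8 false calls. Few probes were changed in the simulation, which makes the adjusted threshold stricter than in the data. These shares therefore do not carry over to the data. There, this comparison called 4533 probes, of which 2126 changed by at least 2-fold, so smaller changes were also called. Camera called both shifted lists and 0 of the others among 9 lists of 5 genes. The simulated genes varied independently, whereas the estimated correlation in the data was 0.44 for the extracellular matrix list and 0.16 for the secretory list. The simulation therefore does not show how often camera calls a list wrongly in the data.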

Results

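The series measured messenger RNA in biopsies of the endometrium, the lining of the uterus, from 5 cycling mares at 5 times of the oestrous cycle. Day 0 was the day of ovulation. The labels call day 0 the ovulatory phase, days 3, 8 and 12 the early, mid and late luteal phase, when the corpus luteum secretes progesterone, and day 16 the beginning of the next ovulatory phase. Each mare gave 1 biopsy per day, taken in different cycles, so that 25 one-colour arrays in 5 groups of 5 were available. Each array held 43803 spots of 43603 probes, and 35770 probes were bright enough to be tested. The 75th percentile of the signal ranged from 698 to 3701 over the 25 arrays, with a median of 895 at day 0, 1720 at day 3, 1559 at day 8, 1868 at day 12 and 2001 at day 16. Between 70.3% and 88.1% of the spots of an array were well above background, and no spot was saturated. The 5 arrays per day limit the precision of each value below. Gene names were available for 538 tested genes. Log2 changes are given with their moderated standard error, the direction being the first day named minus the second. This error comes from the model of all 25 arrays, which shares 1 spread over the 5 days. It is therefore not the spread of the days compared. Every gene named below as risen or fallen did so in all 5 mares unless fewer are stated, and genes with other probes of which none passed are pointed out.

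The first question was how much of the transcriptome changed with the day of the cycle. In limma's moderated F test, 12790 of 35770 probes (35.8%) differed between the 5 days. Their highest mean lay at day 0 for 2788, at day 3 for 3157, at day 8 for 2507, at day 12 for 2269 and at day 16 for 2069 probes. The mares differed most from each other at day 16, where the median SD of a probe between mares was 0.51, and least at day 8, where it was 0.29. Between successive days, 4533 probes changed from day 0 to day 3, 4927 from day 3 to day 8, 392 from day 8 to day 12, 2888 from day 12 to day 16 and 1683 from day 16 to day 0. Leaving out all arrays of mare 2 or of mare 3 lowered the count over the 5 days to 7503 and 7928, and a model with mare and slide gave 7805. It was 6619 with 1 probe per target and 3702 with the planned normexp background correction, under which 111 of 171 changes of named genes lost their call. That correction broke down on the day 8 array of mare 2, where local backgrounds reached 772899, against at most 251 on the other arrays. Replacing the marked backgrounds on this array alone gave 14975 probes and 16 of 171 lost calls, and on all arrays 14500 and 18. The low counts with the planned normexp below therefore come largely from 1 array.

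**Figure D1:**
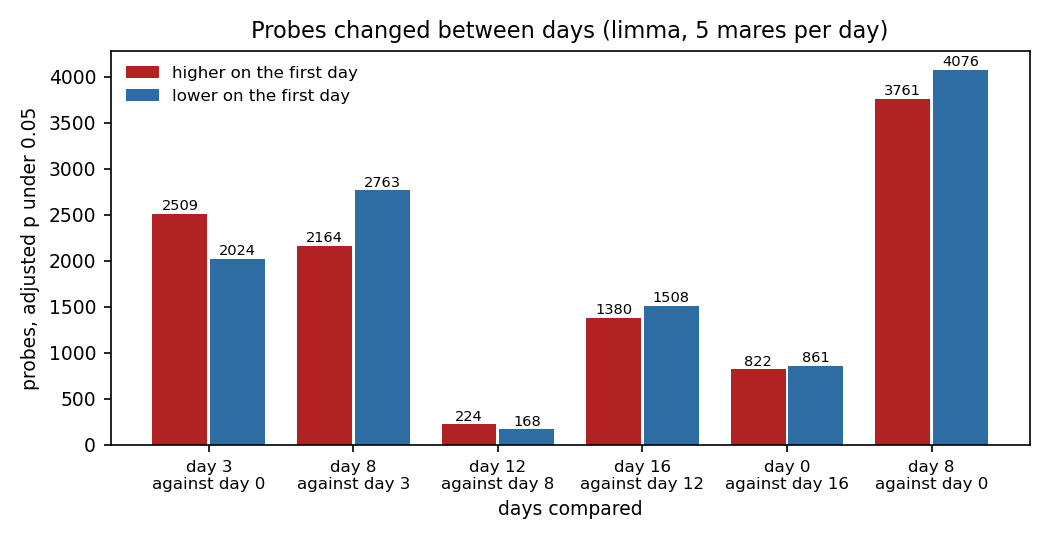
Number of probes changed in each of the 6 comparisons of days (limma, adjusted p under 0.05, 5 mares per day, 35770 probes tested). The bars split them into probes higher and lower on the first day named, from 3761 and 4076 between days 8 and 0 to 224 and 168 between days 12 and 8.

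Of 16 genes of hormone response fixed beforehand, 5 had a named probe. ESR1, the oestrogen receptor alpha, had a mean log2 level of 7.12 ± 0.24 (SD, n = 5) at day 0, 6.67 ± 0.50 at day 3, 6.05 ± 0.19 at day 8, 5.39 ± 0.27 at day 12 and 6.47 ± 0.63 at day 16. It fell by 1.07 ± 0.25 from day 0 to day 8 (adjusted p = 0.00385) and rose by 1.08 ± 0.25 from day 12 to day 16 (adjusted p = 0.00898). Its 5 other probes went the same way in these comparisons but none passed, and after quantile normalization the fall was −0.65 ± 0.25 (adjusted p = 0.0596). P19, which encodes the lipocalin uterocalin that the equine uterus secretes, went from 3.65 ± 0.66 at day 0 over 5.54 ± 1.25 at day 3 to 7.74 ± 0.17 at day 8, 7.49 ± 0.27 at day 12 and 6.35 ± 1.18 at day 16. PTGFR, the receptor of prostaglandin F, stood at −4.32 ± 0.54, −3.55 ± 0.49, −3.87 ± 0.46, −4.50 ± 0.75 and −5.54 ± 1.01 on the same days. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, was at 0.75 ± 0.96, 0.02 ± 0.82, 0.66 ± 0.38, 1.08 ± 0.42 and 1.18 ± 1.08, and no difference between days passed the F test (adjusted p = 0.243). IGF1, a growth factor, was at −3.43 ± 0.67, −3.48 ± 0.87, −3.01 ± 0.40, −3.00 ± 0.52 and −3.58 ± 1.38 (adjusted p = 0.723).

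**Figure D2:**
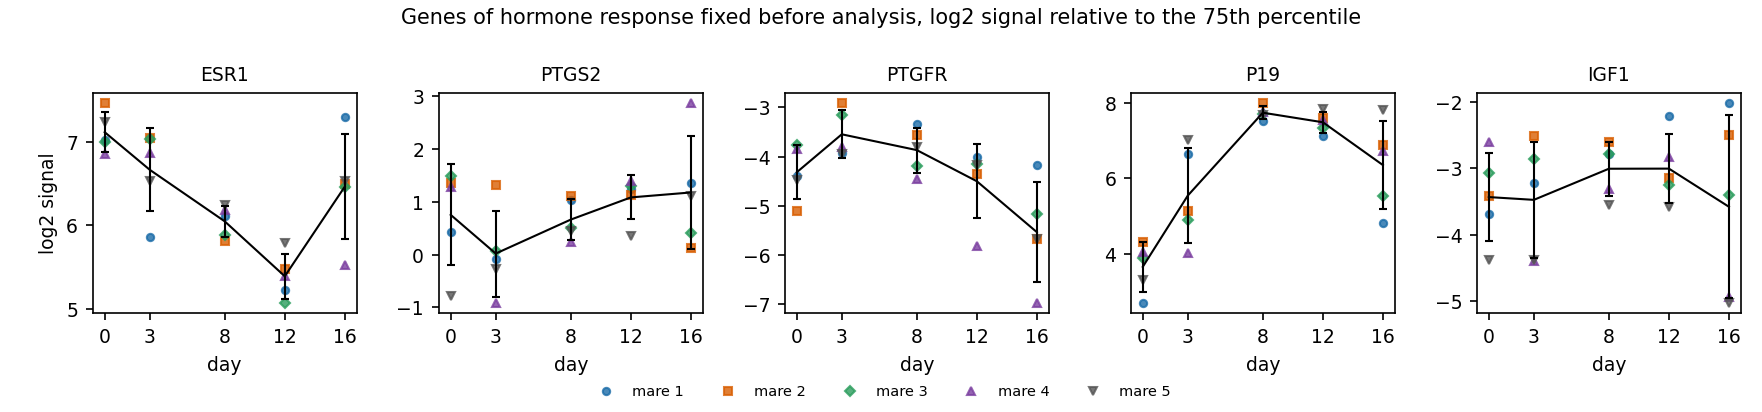
Log2 signal relative to the 75th percentile of each array (y axis) by day of the cycle (x axis) for ESR1, PTGS2, PTGFR, P19 and IGF1, with a point per mare and a line with bars for mean and SD (n = 5). ESR1 has its lowest mean at day 12 (5.39) and P19 its highest at day 8 (7.74).

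From ovulation to the early luteal phase (day 3 against day 0), transcripts of CXC chemokines and of the protease MMP3 were among those that fell. MMP3 (stromelysin, a protease that degrades matrix) fell by 5.03 ± 0.65 and was not well above background on any array at day 3, which makes it at least 14.8-fold lower. The day 0 array of mare 4 lay far above the other 4, and without it the fall was −4.32 and the bound 9.06-fold. Such lower bounds are given wherever all arrays of a day were at background. CXCL6 fell by 3.98 ± 0.95 and CXCL8 was at least 2.43-fold lower (−2.63 ± 0.67). They encode chemokines that attract neutrophils. CXCL10 fell by 2.15 ± 0.35 and CXCL9 by 1.51 ± 0.41, both chemokines induced by interferon. A second probe of CXCL9 did not pass the test. With the planned normexp, 33 of 33 named changes of this comparison lost their call, with MMP3 at −2.06 (adjusted p = 0.150), CXCL6 at −1.95 (0.176), CXCL8 at −0.98 (0.620), CXCL10 at −1.81 (0.0515) and CXCL9 at −1.19 (0.308). With marked backgrounds replaced all 5 passed, MMP3 at −2.15 and CXCL6 at −2.03. Among the genes that rose, FST, whose product follistatin binds activin, rose by 1.54 ± 0.20 (adjusted p = 8.64e-05), HK2, a hexokinase that starts glycolysis, by 1.93 ± 0.30 and TFRC, the transferrin receptor for iron uptake, by 1.92 ± 0.51. With marked backgrounds replaced TFRC was at 0.17 (adjusted p = 0.598), and with slide as a block it did not pass (adjusted p = 0.0585).

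Of the 538 named genes tested, 32 rose and 48 fell from day 0 to day 3. LGB1, a beta-lactoglobulin of the lipocalin family, was at background on all arrays at day 0 and well above it on 4 of 5 at day 3, at least 1.98-fold higher (2.86 ± 0.53). It reversed to −0.029 with the planned normexp background correction and to −0.054 with normexp after marked local backgrounds had been replaced. These variants add an offset of 50, which by construction lowers the log2 changes of dim probes. Other large rises were those of GJB1, a gap junction protein (1.38 ± 0.27), PTGES, a prostaglandin E synthase (1.38 ± 0.36). Rises of similar size were those of ITGA2B, an integrin chain (1.31 ± 0.26), POR, the electron donor of cytochromes P450 (1.23 ± 0.33), RNASEH2C (1.1 ± 0.34) and JPT2 (1.04 ± 0.24). Other large falls were those of CLEC3A (−4.39 ± 0.78, at least 5.47-fold lower), CHGA, chromogranin A of secretory granules (−3.02 ± 0.91, above background on 1 of 5 arrays at day 3), LILRA, a leukocyte receptor (−2.55 ± 0.80, 1 of 5 arrays), PPARGC1A, a regulator of mitochondrial formation (−1.71 ± 0.40) and MMP9, a gelatinase (−1.51 ± 0.49). With marked backgrounds replaced CHGA was at −1.34 (adjusted p = 0.159). MMP9 did not pass with quantile normalization (adjusted p = 0.0665) or slide as a block (0.131).

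Of the 42 members of the extracellular matrix list, only 5 had a named probe. All 5 fell from day 0 to day 3, also when adjusted over the list alone. Their median was −1.09 (camera adjusted p = 0.00907, and 0.497 with an estimated correlation). LUM fell by 1.32 ± 0.35, SPARC by 1.24 ± 0.16, DCN by 1.09 ± 0.26 and BGN by 0.85 ± 0.24 in 4 of 5 mares. LUM, DCN and BGN encode proteoglycans that bind collagen. The fifth member, COL5A2, a collagen chain named after its values were seen, fell by 0.73 ± 0.20. With quantile normalization, BGN (adjusted p = 0.0597) and COL5A2 (0.134) did not pass, nor did BGN with slide as a block (0.0594). The list's median was −0.59, −1.31 and −0.75 within the 3 slides that held both days. Without mare 4 it was −1.24 (adjusted p = 0.0798), and 5 of 100 splits of the 10 arrays gave a camera p as small as the real days. LUM and DCN are also the tested markers of stromal fibroblasts. The marker of epithelium, ESRP1, was at −0.19 ± 0.18, that of endothelium, PECAM1, at −0.11 ± 0.19 and that of ciliated cells, DYDC1, at −1.02 ± 0.35, none of which passed the test.

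In the other lists of this comparison, single members changed while the list as a whole did not pass. Of 10 interferon-stimulated genes, CXCL9 and CXCL10 fell and 8 did not pass (3 fell adjusted over the list alone; camera adjusted p = 0.169). Of 6 proteases of matrix turnover and their inhibitors, MMP3 and MMP9 fell (2 adjusted over the list alone; adjusted p = 0.348). Of 11 genes of antimicrobial defence CXCL6 and CXCL8 fell (2 adjusted over the list alone; adjusted p = 0.743). Of 9 prostaglandin and oxytocin genes, PTGES rose and HPGD, which inactivates prostaglandins, fell by 1.34 ± 0.34, the same 2 when adjusted over the list alone (adjusted p = 0.608). Of 9 uterine secretory proteins, P19 rose by 1.89 ± 0.50 in 4 of 5 mares and B2M fell by 0.94 ± 0.19 (1 rose and 2 fell adjusted over the list alone; adjusted p = 0.992). FRZB, a secreted WNT antagonist, fell by 1.06 ± 0.24 as 1 of 5 WNT genes (1 adjusted over the list alone; adjusted p = 0.608). MET, the receptor of hepatocyte growth factor, fell by 1.06 ± 0.28 in 4 of 5 mares (none of 2 other probes passing) as 1 of 3 growth factor genes (1 adjusted over the list alone; adjusted p = 0.870). HSD3B2, a steroid dehydrogenase, rose by 1.73 ± 0.46 in 4 of 5 mares as 1 of 10 sterol and steroid genes (1 adjusted over the list alone; adjusted p = 0.870). HSD3B2 was at 0.41 with marked backgrounds replaced (adjusted p = 0.297), HPGD did not pass with quantile normalization (0.0527) or slide (0.0585), and MET did not with slide (0.0658).

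Over all probes, limma called 2509 higher and 2024 lower at day 3 than at day 0, 1154 and 972 of them by at least 2-fold. The median of all probes was −0.11, against 0.01 after quantile normalization, which called 3273 higher and 1722 lower. Within the 3 slides that held both days, 83.0%, 99.2% and 98.1% of the called probes went the pooled way. Here and below, the arrays of these slides also entered the calls, which raises such percentages. The day 0 array was dimmer than the day 3 array in every mare, so a lower signal at day 0 cannot be told apart from a change with the day. Of 33 named changes, 19 lost their call with the signal level of the array as a covariate and 27 with mare and slide. The count was 732 with mare and slide in the model, 1387 with only these days, 1658 with the signal level of the array as a covariate and 2367 with 1 probe per target. It was 344 with the planned normexp and 8525 (6377 lower) with marked backgrounds replaced, and slide as a block gave 2109 higher and 3092 lower. Leaving out mares 1 to 5 gave 1512, 1631, 2191, 6415 and 2063. Without the day 0 array of mare 2 it was 2772, without the day 3 array of mare 1 it was 2497 and without that of mare 5 it was 2825. Without the arrays that stand apart (day 0 of mare 2, day 3 of mare 4) it was 3628. This pair was chosen after the values were seen, by no rule fixed beforehand, and its name states no test result.

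From the early to the mid luteal phase (day 8 against day 3), cytochromes P450 were among the genes that rose most. CYP3A97 and CYP3A89, cytochromes P450 of steroid and drug oxidation, rose by 5.52 ± 0.59 and 4.73 ± 0.55 (adjusted p = 3.60e-06 and 8.29e-06), CYP3A97 from background on 4 of 5 arrays at day 3. They are close relatives, and whether the probes tell them apart was not tested. CYP2E1, another cytochrome P450, rose by 3.40 ± 0.80. INHBA, a subunit of activin and inhibin, rose by 2.79 ± 0.52, and P19 by 2.20 ± 0.50. The phospholipases PLA2G2A and PLA2G4A, which release fatty acids such as the precursor of prostaglandins, fell by 1.68 ± 0.48 and 1.60 ± 0.27.

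Of the named genes, 37 rose and 39 fell from day 3 to day 8. Further large rises were those of SAA, the acute phase protein serum amyloid A (5.08 ± 1.42), CTTNBP2 (2.29 ± 0.21) and LGB1 (1.92 ± 0.53). CYP19A1, the aromatase that makes oestrogens, rose by 1.86 ± 0.53, and PLIN2, which coats lipid droplets, by 1.70 ± 0.19. Further large falls were those of CFTR, a chloride channel (−1.69 ± 0.39), RNASEH2C (−1.65 ± 0.34), CADM1, a cell adhesion protein (−1.44 ± 0.25), SPRED1 (−1.27 ± 0.23), MYH7, a myosin heavy chain (−1.19 ± 0.37), COX10 (−1.15 ± 0.22, but 0.15 with the planned normexp) and RND3 (−1.12 ± 0.29). Of 9 prostaglandin and oxytocin genes, 1 rose, PTGER2, a receptor of prostaglandin E (1.19 ± 0.39), and the 2 phospholipases fell (1 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.743). Of 7 transporters, SLC2A5, which carries fructose, rose by 1.49 ± 0.38, while 2 fell, CFTR among them (1 and 2 adjusted over the list alone; adjusted p = 0.663). Of 9 uterine secretory proteins, P19 and GM2A (0.85 ± 0.28) rose (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.608). FST rose by 1.08 ± 0.20 as 1 of 3 genes of progesterone response (1 adjusted over the list alone; adjusted p = 0.608). CD44, a receptor of hyaluronan, fell by 1.06 ± 0.22 as 1 of 4 genes of junctions and integrins (1 adjusted over the list alone; adjusted p = 0.811). GM2A did not pass with quantile normalization (adjusted p = 0.0533), nor MYH7 with slide as a block (0.0766).

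Over all probes, limma called 2164 higher and 2763 lower at day 8 than at day 3, 1323 and 1133 of them by at least 2-fold. Within the 4 slides that held both days, 98.1% to 99.6% of the called probes went the pooled way. The count was 1756 with the planned normexp background correction, 2611 with 1 probe per target, 3090 without mare 2, 3181 without mare 4, and 3993 without the 2 arrays that stand apart.

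From the mid to the late luteal phase (day 12 against day 8), few named genes changed, and most of these rose. CHGA rose by 5.27 ± 0.91 (adjusted p = 0.00797), DEFB4B, a beta-defensin that kills microbes, by 4.88 ± 1.2, RBP4, the carrier of retinol, by 2.92 ± 0.46, and GSN, the actin-severing gelsolin, by 1.59 ± 0.25. SLC2A5 fell by 1.83 ± 0.38 and RRAGA, a GTPase of nutrient sensing, by 0.69 ± 0.13. In all, 11 named genes rose and 2 fell. Of 12 changes followed under the alternatives, 12 lost their call with mare and slide in the model.

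The other rises were those of GNLY, the cytolytic granulysin (1.23 ± 0.27), GM2A, a lysosomal lipid carrier (1.19 ± 0.28), CCL5, a chemokine of T cells (0.97 ± 0.24, a second probe not passing), and FTL, the light chain of ferritin (0.90 ± 0.18). UBE2B rose by 0.71 ± 0.17. BDNF, a neurotrophin, rose by 1.80 ± 0.43, above background on 2 of 5 arrays at day 8, its other 4 probes did not pass, and it reversed to −0.63 with the planned normexp. Of 9 uterine secretory proteins, RBP4 and GM2A rose (2 adjusted over the list alone; camera adjusted p = 0.185). Of 4 markers of T and NK cells CCL5 rose (1 adjusted over the list alone; adjusted p = 0.169). Of 7 transporters SLC2A5 fell (3 adjusted over the list alone; adjusted p = 0.0616). DEFB4B, BDNF and UBE2B did not pass with quantile normalization (adjusted p = 0.0520, 0.111 and 0.111), nor BDNF and CCL5 with slide as a block (0.0528 and 0.0556) or with marked backgrounds replaced (0.657 and 0.0662).

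Over all probes, limma called 224 higher and 168 lower at day 12 than at day 8, 158 and 124 of them by at least 2-fold. All 392 went the pooled way within each of the 3 slides that held both days. With the mare as a block the count was 855, with mare and slide 4, with only these days 2409, with the array's signal level as a covariate 238, with the planned normexp 18, with quantile normalization 606, without a filter on dim probes 213, with 1 probe per target 187, and without the arrays that stand apart 413. Without the day 12 array of mare 5 it was 474, and without any other single array of these days it was between 33 (day 8 of mare 3) and 238 (day 8 of mare 1). It was 3 without mare 2 and 0 without mare 3, where 3368 probes had an unadjusted p under 0.05 by limma. With only these days, the median standard error was 0.208, against 0.281 with all days in 1 model.

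From the late luteal phase to the beginning of the next ovulatory phase (day 16 against day 12), MMP3, 2 phospholipases and the chemokines CCL2, CXCL8 and CXCL10 were among the genes that rose, and CYP3A97 and CYP3A89 among those that fell. MMP3 rose by 4.02 ± 0.65 (1 of 5 arrays above background at day 12), PLA2G2A by 3.21 ± 0.48 and PLA2G4A by 1.96 ± 0.27 (adjusted p = 6.02e-05). CCL2, a chemokine of monocytes, rose by 1.92 ± 0.37, and CXCL8 was at least 2.01-fold higher (2.93 ± 0.67, 3 of 5 arrays above background at day 16, and a bound of 1.07-fold without the day 16 array of mare 4). With marked backgrounds replaced, MMP3 was at 0.83 (adjusted p = 0.204) and CXCL8 at 0.60 (0.261). CYP3A97 fell by 5.22 ± 0.59 and LGB1 by 3.38 ± 0.53, each above background on 1 of 5 arrays at day 16, CYP3A89 by 4.09 ± 0.55 and FST by 2.69 ± 0.20 (adjusted p = 1.15e-08).

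Of the named genes, 41 rose and 18 fell from day 12 to day 16. Further large rises were those of SPI2, a serine protease inhibitor (4.15 ± 0.86), IL1R2, a decoy receptor of interleukin 1 (2.16 ± 0.66, 1 of 5 arrays at day 12), MYH7 (1.94 ± 0.37) and CFTR (1.79 ± 0.39). Further large falls were those of CTTNBP2 (−2.17 ± 0.21), INHA, the alpha subunit of inhibin (−1.81 ± 0.46), POR (−1.80 ± 0.33), PLIN2 (−1.44 ± 0.19), HK2 (−1.34 ± 0.30) and HTR1B, a serotonin receptor (−1.31 ± 0.38). IL1R2 and HTR1B did not pass with slide as a block (adjusted p = 0.0720 and 0.0810), nor IL1R2 (0.59) and INHA (−0.85) with marked backgrounds replaced (0.167 and 0.0764). Of 5 extracellular matrix genes, LUM and SPARC rose by 1.64 ± 0.35 and 0.66 ± 0.16 (4 adjusted over the list alone; camera adjusted p = 0.0616). Of 10 interferon-stimulated genes, 2 rose, among them CXCL10 by 1.53 ± 0.35 (2 adjusted over the list alone; adjusted p = 0.225). Of 6 proteases and inhibitors, MMP3 and TIMP1, an inhibitor of metalloproteases (1.59 ± 0.31), rose (3 adjusted over the list alone; adjusted p = 0.263). Of 9 prostaglandin and oxytocin genes the 2 phospholipases rose (2 rose and 2 fell adjusted over the list alone; adjusted p = 0.886). CD44 rose by 1.12 ± 0.22 as 1 of 4 genes of junctions and integrins (1 adjusted over the list alone; adjusted p = 0.845). RSPO3, a WNT agonist, rose by 1.19 ± 0.32 (its other probe not passing) as 1 of 5 WNT genes (1 adjusted over the list alone; adjusted p = 0.663).

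Over all probes, limma called 1380 higher and 1508 lower at day 16 than at day 12, 832 and 980 of them by at least 2-fold. Within the 3 slides that held both days, 96.3%, 99.7% and 98.7% of the called probes went the pooled way. The count was 1733 with mare and slide, 1519 with only these days, 674 with the planned normexp, 1470 with 1 probe per target, 1253 without mare 2, 1345 without mare 3 and 3077 without the arrays that stand apart.

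Between the beginning of the ovulatory phase and ovulation itself (day 0 against day 16), CHGA had the largest change of the named genes. CHGA fell by 6.98 ± 0.91 (adjusted p = 0.000287), CYP2E1 by 3.74 ± 0.80, P19 by 2.70 ± 0.50, RBP4 by 2.41 ± 0.46 and VEGFA, the growth factor of blood vessels, by 2.07 ± 0.36. COL11A1, a collagen chain, rose by 2.69 ± 0.73 (its other probe not passing), and KLK1E2 and KLK1, kallikrein proteases that are close relatives, by 1.99 ± 0.50 (3 of 5 arrays above background at day 16) and 1.33 ± 0.35. COL11A1 did not pass with quantile normalization (adjusted p = 0.0737) or slide as a block (0.0843), nor KLK1 with slide (0.0715). Of 26 named changes of this comparison, 25 lost their call with the array's signal level as a covariate. With mare and slide 23 lost it, and without the arrays that stand apart 15 did.

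Of 9 uterine secretory proteins with a named probe, out of 35 in the list, 4 fell from day 16 to day 0. The other 5 did not pass (5 fell adjusted over the list alone). The list's median was −1.66 (camera adjusted p = 0.0106; adjusted p = 0.497 with an estimated correlation). The 4 were P19, RBP4, GM2A (−1.77 ± 0.28) and GPX3, a secreted glutathione peroxidase (−1.66 ± 0.41, 4 of 5 mares). The list's median was −2.40, −2.54 and −0.84 within the 3 slides that held both days. With the array's signal level as a covariate it was −1.35 (adjusted p = 0.0665), and without the day 0 array of mare 4 it was −1.42 (adjusted p = 0.0879), and without mare 4 it was −1.47 (adjusted p = 0.125). Of 100 splits of the 10 arrays, 5 gave a camera p as small as the real days.

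Of the named genes, 20 rose and 23 fell from day 16 to day 0. Further large rises were those of SLC16A1, a carrier of lactate (1.22 ± 0.24, its other probe not passing), NKAIN2 (1.21 ± 0.33), BGN (0.96 ± 0.24), RPL5 (0.88 ± 0.20), FRZB (0.85 ± 0.24) and SERPINF1 (0.79 ± 0.19). The ribosomal protein RPLP2 rose by 0.72 ± 0.20 and made with RPL5 2 of 3 ribosomal proteins that rose (2 adjusted over the list alone; camera adjusted p = 0.136), but after quantile normalization RPLP2 was at −0.034 and RPL5 at 0.15 (adjusted p = 0.932 and 0.510). NKAIN2 (0.0716), BGN (0.0568) and CCL2 (0.0680) did not pass with quantile normalization either, nor BGN, FRZB, TFRC, TAGLN and the 2 ribosomal proteins with slide as a block. Further large falls were those of TFRC (−2.25 ± 0.51), CCL2 (−1.35 ± 0.37), S100A6 (−1.18 ± 0.28) and TAGLN, an actin-binding marker of smooth muscle (−1.16 ± 0.32). Of 5 extracellular matrix genes BGN and SPARC (0.62 ± 0.16, none of 7 other probes passing and 2 of them rising) rose (2 adjusted over the list alone; adjusted p = 0.169), but SPARC was at 0.26 after quantile normalization (adjusted p = 0.483) and did not pass with slide (0.0638). Of 6 proteases and inhibitors, MMP9 rose by 1.78 ± 0.49 and TIMP1 fell by 1.06 ± 0.31, each in 4 of 5 mares (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.933), of which MMP9 did not pass with quantile normalization (0.0557) and neither did with slide (0.106 and 0.0513). TFRC was at −0.36 with marked backgrounds replaced (adjusted p = 0.255). PTGES fell by 1.22 ± 0.36 in 4 of 5 mares, which did not pass with the mare as a block (adjusted p = 0.0555), as 1 of 9 prostaglandin and oxytocin genes (2 rose and 1 fell adjusted over the list alone; adjusted p = 0.906). GJB1 fell by 1.08 ± 0.27 as 1 of 4 genes of junctions and integrins (1 adjusted over the list alone; adjusted p = 0.544).

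Over all probes, limma called 822 higher and 861 lower at day 0 than at day 16, 391 and 577 of them by at least 2-fold. Quantile normalization gave 539 and 949. The day 0 arrays were dimmer, with a median 75th percentile of 895 against 2001. Within the 3 slides that held both days, 97.4%, 98.9% and 99.5% of the called probes went the pooled way, and 80.8%, 92.2% and 97.7% of those called without the arrays of the slide. The count was 9 with the array's signal level as a covariate, 48 with only these days, 152 with mare and slide, 69 with the planned normexp, 7895 (6821 higher) with marked backgrounds replaced, 3300 without a filter on dim probes, 761 with 1 probe per target, and 928 without the arrays that stand apart. It was 883 without the day 0 array of mare 2, and 3204, 942 and 1082 without the day 16 arrays of mares 1, 2 and 4. Leaving out mares 1 to 5 gave 3025, 108, 341, 1106 and 758, and slide as a block gave 1461 higher and 683 lower.

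**Figure D3:**
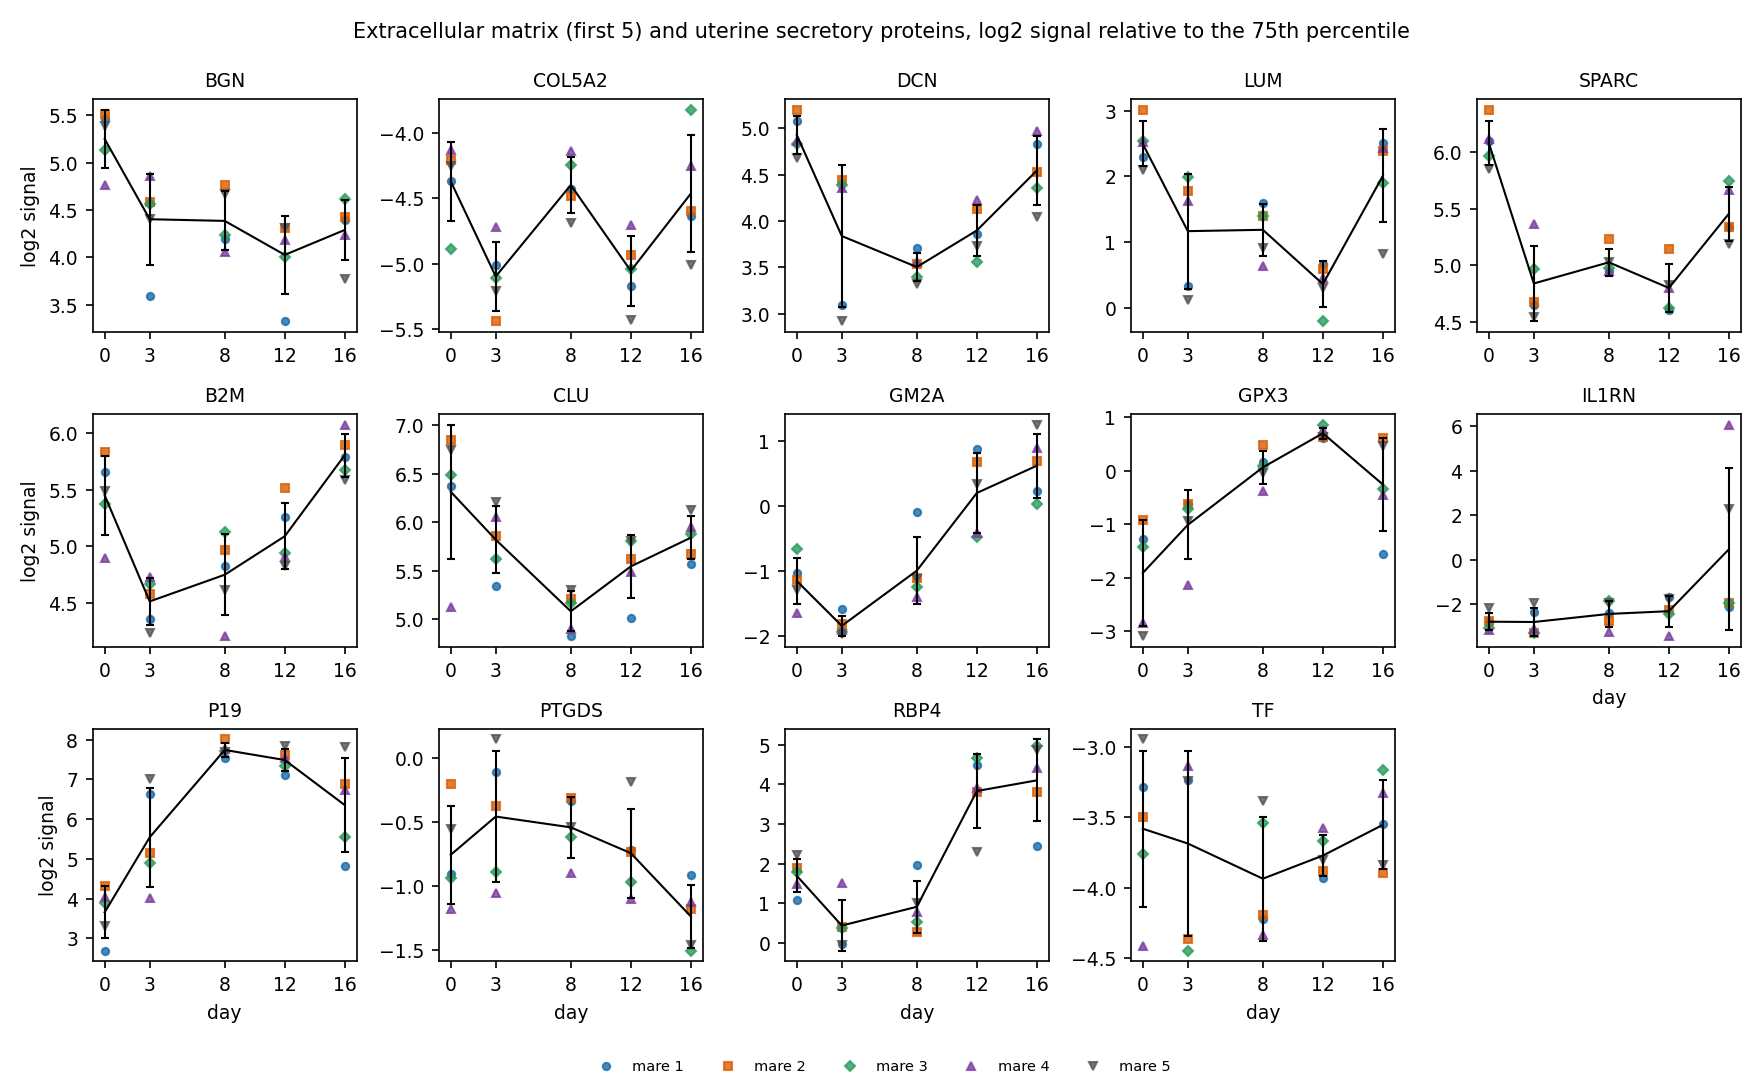
Log2 signal relative to the 75th percentile of each array (y axis) by day of the cycle (x axis) for the 5 extracellular matrix genes and the 9 uterine secretory proteins, with a point per mare and a line with bars for mean and SD (n = 5). The 5 matrix genes have lower means at day 3 than at day 0, and P19, RBP4, GM2A and GPX3 have lower means at day 0 than at day 16.

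Of the 6 comparisons, that of the mid luteal phase with ovulation (day 8 against day 0) called the most probes in the day-only model. With mare and slide, day 8 against day 3 called more (3485 against 2425). With marked backgrounds replaced, day 3 against day 0 (8525) and day 0 against day 16 (7895) called more than its 7303. That variant adds an offset of 50, which weighs more on the dimmer day 0 arrays. CYP3A89 was higher at day 8 by 6.06 ± 0.55 (adjusted p = 8.08e-08) and CYP3A97 by 5.23 ± 0.59, above background on 1 of 5 arrays at day 0. P19 was higher by 4.09 ± 0.50, LGB1 at least 7.48-fold (4.78 ± 0.53), and FST by 2.62 ± 0.20 (adjusted p = 1.25e-08). Such bounds were computed for the main background correction only. MMP3 was at least 13.1-fold lower at day 8 (−5.83 ± 0.65), but its day 0 mean included mare 4, far above the others, without whose day 0 array the change was −5.12 and the bound 8.01-fold. CXCL6 was lower by a log2 change of −4.71 ± 0.95 (2 of 5 arrays above background at day 8) and MMP9 of −2.78 ± 0.49.

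Of the named genes, 48 were higher and 86 lower at day 8 than at day 0. Further large rises were those of CYP2E1 (3.23 ± 0.80), HK2 (2.91 ± 0.30), CTTNBP2 (2.67 ± 0.21), INHBA (2.33 ± 0.52) and HSD3B2 (2.32 ± 0.46, 3 of 5 arrays above background at day 0). Further large falls were those of CLEC3A (−4.04 ± 0.78, at least 4.83-fold lower), SPI2 (−3.81 ± 0.86), CXCL8 (−2.86 ± 0.67, at least 2.15-fold lower, but 0.015 with the planned normexp), MYH7 (−2.75 ± 0.37), RND3 (−2.20 ± 0.29) and PLA2G4A (−2.15 ± 0.27). Of 5 extracellular matrix genes 4 fell, with LUM at −1.30 ± 0.35, SPARC at −1.05 ± 0.16, DCN at −1.43 ± 0.26 and BGN at −0.87 ± 0.24 (4 adjusted over the list alone; camera adjusted p = 0.139). Of 10 interferon-stimulated genes, CXCL10 (−2.11 ± 0.35), CXCL9 (−1.17 ± 0.41, 4 of 5 mares, its other probe not passing) and OAS2, an antiviral enzyme (−0.98 ± 0.31, 4 of 5 mares, none of 5 other probes passing), fell (3 adjusted over the list alone; adjusted p = 0.541). Of 9 prostaglandin and oxytocin genes, PTGER2 rose by 2.03 ± 0.39 and PTGES by 1.46 ± 0.36, and PLA2G4A fell (2 rose and 3 fell adjusted over the list alone; adjusted p = 0.906). Of 9 uterine secretory proteins, P19 and GPX3 (1.98 ± 0.41) rose, and CLU (−1.23 ± 0.25) and B2M (−0.70 ± 0.19) fell (2 and 2 adjusted over the list alone; adjusted p = 0.754). Of 6 genes of blood vessel growth, VEGFA (1.28 ± 0.36) and HEY1 (0.75 ± 0.24) rose and EDNRA, an endothelin receptor (−1.57 ± 0.33), fell (2 and 1 adjusted over the list alone; adjusted p = 0.886). FRZB and RSPO3 fell by 0.97 ± 0.24 and 1.04 ± 0.32 (RSPO3 in 4 of 5 mares) as 2 of 5 WNT genes (2 adjusted over the list alone; adjusted p = 0.608). B2M did not pass with quantile normalization (adjusted p = 0.0776), nor CYP2E1 (1.67), HSD3B2 (0.84), CXCL8 (−0.81) and VEGFA (0.21) with marked backgrounds replaced (adjusted p = 0.0653, 0.0502, 0.0523 and 0.525).

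**Figure D4:**
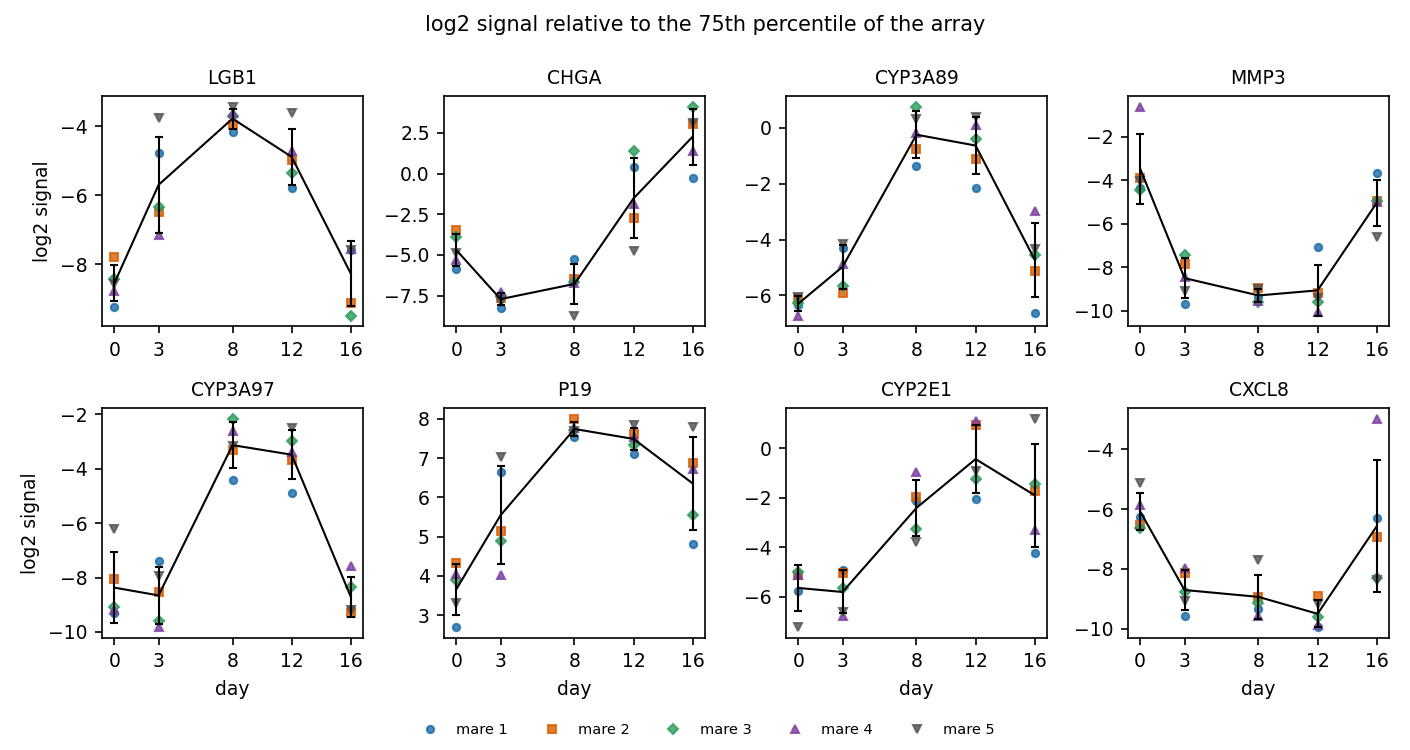
Log2 signal relative to the 75th percentile of each array (y axis) by day of the cycle (x axis) for 8 of the genes named in the most comparisons, with a point per mare and a line with bars for mean and SD (n = 5). CYP3A89, CYP3A97, LGB1 and P19 have their highest means at day 8, MMP3 its highest at day 0, and CHGA its highest at day 16 (2.28).

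Over all probes, limma called 3761 higher and 4076 lower at day 8 than at day 0, 2323 and 1854 of them by at least 2-fold. The probe with the largest rise matched LOC100061179, an uncharacterised locus, and was at background at day 0, at least 319-fold lower than at day 8. It was chosen after the values were seen. Within the 2 slides that held both days, 99.04% and 98.8% of the called probes went the pooled way. The count was 2425 with mare and slide, 2523 with the planned normexp, 4152 with 1 probe per target, 4605 without mare 2 and 6888 without the arrays that stand apart. With the signal covariate it was 7375, the day 0 array being dimmer than the day 8 array in every mare. Of 43 named changes, 26 lost their call with mare and slide, 21 with the planned normexp and 3 with the signal covariate.

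The last question was whether probes that moved after ovulation moved back when the luteal phase ended. Of the 2509 probes that rose from day 0 to day 3, 466 fell from day 12 to day 16, where 105.8 would be shared by independent lists of these sizes. Of the 2024 that fell, 336 rose from day 12 to day 16 (78.1 for independent lists). In the same direction, 64 probes rose in both steps (96.8 for independent lists) and 50 fell in both (85.3). These comparisons share no array but do share the mares. Among the named genes, LGB1, FST, HK2 and POR rose after ovulation and fell at the end of the luteal phase, and MMP3, CXCL8, CXCL10 and LUM did the opposite. The 802 probes called in opposite directions became 162 with mare and slide, 64 with the planned normexp, 442 with the signal covariate, 408 with 1 probe per target and 803 without the arrays that stand apart. They were 300, 230, 308 and 381 without mares 1, 2, 3 and 5.

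**Figure D5:**
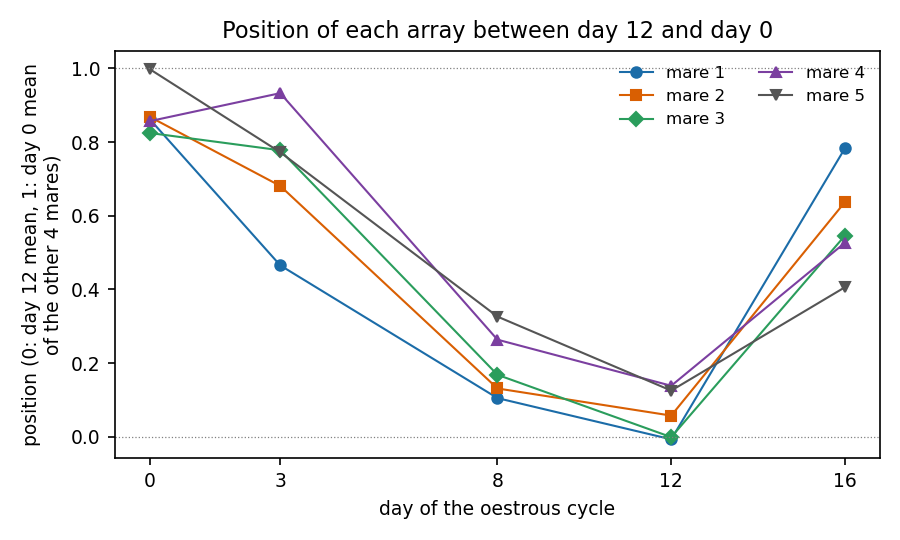
Position of each array on a line from the mean of day 12 (0) to the mean of day 0 (1), both taken from the other 4 mares (y axis), by day of the cycle (x axis), with a line per mare. At day 16 the mares lie between 0.41 and 0.78, and at day 3 between 0.47 and 0.93.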

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

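The tests of slides and of exchanged arrays for the differences between days 0 and 16 were chosen after the results were seen. Among 140 groups of 5 arrays, 9 held a value far from the other 4 by Dixon's criterion, where about 1 in 20 by chance, or 7, would. Mare 4 gave 4 of them. At day 0 its MMP3 level was −0.62 (others −4.43 to −3.89) and its CLU level 5.13 (others 6.37 to 6.84), at day 3 its GPX3 level was −2.15 (others −0.95 to −0.63), and at day 12 its PTGFR level was −5.82 (others −4.35 to −4.02). Mare 2 at day 0 had 70.3% of spots well above background (others 78.0% to 79.9%). The GM2A level of mare 1 at day 8 was −0.094 (others −1.40 to −1.11), and the PTGS2 level of mare 5 at day 12 was 0.36 (others 1.12 to 1.39). The 75th percentile of the signal of mare 1 at day 3 was 2492 (others 1601 to 1834). On the line from day 12 to day 0, mare 5 at day 0 lay at 0.997 (others 0.82 to 0.87).

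The mares differed more from each other at days 3 and 16 than at day 8, with ratios of the median SD of 1.56 and 1.78. This was not particular to those days, as the median SD was 0.44 at day 0, close to the 0.45 of day 3. It was 0.35 at day 12 and lowest at day 8, at 0.29. The ratios tested below leave day 0 out. Noise of dim probes is argued against by the lower of these ratios among the 8943 brightest probes, 1.55. Slide differences are argued against for day 3 by a ratio of 1.86 among 3 mares whose day 3 and day 8 arrays shared a slide. For day 16 they were not tested. Mares sampled at unlike points of the same course may account for part of it. Removing each array's position on that course lowered the day 16 ratio from 1.78 to 1.59 and the day 3 ratio to 1.37. The position was removed along straight lines between day means of the other mares, so whether unlike timing accounts for the rest cannot be told. Differences between the cycles or the mares themselves stay open and untested.

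The 1683 probes called between day 0 and day 16 depended on which mares were included. Of 3023 probes called without mare 1, 55.5% went the same way in mare 1, the mare whose day 0 array was brighter (75th percentile 1556) than its day 16 array (875). A lower signal of the day 0 arrays therefore cannot be told apart from a change with the day, since only 1 mare has the reverse order of brightness. An exchange of the day 0 and day 16 arrays of mare 1 cannot be told apart from a real difference between mares, since the same 55.5% went the same way but exchanging them raised the count from 1683 to 1824. Slide differences are argued against, as 80.8%, 92.2% and 97.7% of the probes called without slides 4, 5 and 6 went the same way within them.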

How the results depend on the processing

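The normexp variants with replaced backgrounds, the signal covariate, leaving out the arrays that stand apart and all alternatives for the overlap were chosen after the results were seen. Except where a construction is named, the cause was not tested. The order below is the 5 days, then days 3 and 0, 8 and 3, 12 and 8, 16 and 12, 0 and 16, 8 and 0, then the 802 opposite calls. With a stricter filter or an intensity trend, no count left 1.5 times the reported one. Between 70.3% and 88.1% of spots were well above background, and the folds of dim probes are limited by background.

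All normexp variants added an offset of 50, which weighs more on the dimmer day 0 arrays. Their unequal counts of higher and lower probes against day 0 therefore cannot be put down to background correction alone. The planned normexp gave 3702, 344, 1756, 18, 674, 69 and 2523 probes and 64 opposite calls. It broke down on the day 8 array of mare 2, with local backgrounds up to 772899 (at most 251 elsewhere). Replacing the marked ones on this array alone gave 14975, 6979, 4236, 377, 2745, 9037 (7906 higher) and 7851 probes and 749 opposite calls. With marked local backgrounds replaced on all 25 arrays (211 to 2540 each), the 5 days gave 14500, opposite calls were 779, days 3 and 0 gave 8525 (2148 higher, 6377 lower) and days 0 and 16 gave 7895 (6821 higher, 1074 lower), and days 8 and 0 gave 2612 higher and 4691 lower. Quantile normalization gave 606 for days 12 and 8, 3273 higher and 1722 lower for days 3 and 0, and 539 and 949 for days 0 and 16. Without a filter, days 12 and 8 gave 213, days 0 and 16 gave 3300, and 4 list tests passed. With slide as a block, days 3 and 0 gave 2109 higher and 3092 lower, and days 0 and 16 gave 1461 and 683. With the mare as a replicate block, days 12 and 8 gave 855 and PTGES between days 0 and 16 lost its call (−1.22, adjusted p = 0.0555). The replicate block changed no other call of a named gene or list and moved no other count by over 1.5 times. The replicate block with slide gave 7805 over the 5 days, 732 for days 3 and 0, 4 for days 12 and 8, 1733 for days 16 and 12, 152 for days 0 and 16, 2425 for days 8 and 0 (under the 3485 for days 8 and 3) and 162 opposite calls. Its median standard error between days 0 and 16 was 1.24 times the day-only one, which fits fewer arrays per term as part of the loss. With only the days compared, the counts were 1387 for days 3 and 0, 2409 for days 12 and 8, 1519 for days 16 and 12 and 48 for days 0 and 16. This setting has fewer arrays and takes the spread from these days alone. The median standard error went from 0.281 to 0.208 for days 12 and 8 and from 0.281 to 0.311 for days 0 and 16. The median SD between mares was 0.29 and 0.35 at days 8 and 12, and 0.44 and 0.51 at days 0 and 16. The shared spread was thus too wide for the former and too narrow for the latter. A 2-fold minimum, stricter by construction, gave 2126 for days 3 and 0, 2456 for days 8 and 3, 282 for days 12 and 8, 1812 for days 16 and 12, 968 for days 0 and 16 and 4177 for days 8 and 0. With 1 probe per target, fewer being tested, the counts in the above order were 6619, 2367, 2611, 187, 1470, 761, 4152 and 408. With the signal covariate, days 3 and 0 gave 1658, days 12 and 8 gave 238, days 0 and 16 gave 9, opposite calls 442, and 1 list test passed, with the secretory list at −1.35 (adjusted p = 0.0665). Without the arrays that stand apart, days 0 and 16 gave 928. Camera with an estimated correlation called 0 lists (6 of 102 at an unadjusted p under 0.05), the extracellular matrix list at −1.09 and the secretory list at −1.66 (adjusted p = 0.497 for both).

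Leaving out 1 array gave 11450 to 13967 over the 5 days, 2497 to 5285 for days 3 and 0, 3658 to 4634 for days 8 and 3, 33 to 474 for days 12 and 8, 2102 to 3155 for days 16 and 12, 883 to 3204 for days 0 and 16 and 6409 to 7954 for days 8 and 0. Days 3 and 0 gave 2772 without day 0 of mare 2, 2497 without day 3 of mare 1 and 2825 without day 3 of mare 5. Days 0 and 16 gave 883 without day 0 of mare 2 and 3204, 942 and 1082 without day 16 of mares 1, 2 and 4. Days 12 and 8 gave 238, 116, 33, 48 and 130 without day 8 of mares 1 to 5, and 67, 208, 38 and 129 without day 12 of mares 1 to 4. The matrix list lay between −1.23 and −0.86 (adjusted p up to 0.0406) and the secretory list between −1.87 and −1.36, at −1.42 (adjusted p = 0.0879) without day 0 of mare 4.

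Leaving out 1 mare gave 7503 (mare 2) to 11329 over the 5 days, with 7928 without mare 3. Days 3 and 0 gave 1512, 1631, 2191, 6415 and 2063 without mares 1 to 5. Days 8 and 3 gave 3090 (mare 2) to 3635, with 3181 without mare 4. Days 12 and 8 gave 116, 3, 0, 115 and 147, the 0 by limma with 3368 probes at an unadjusted p under 0.05. Days 16 and 12 gave 1253 (mare 2) to 2335, with 1345 without mare 3. Days 0 and 16 gave 3025, 108, 341, 1106 and 758, and days 8 and 0 gave 4605 (mare 2) to 7454. Opposite calls were 230 (mare 2) to 793, with 300, 308 and 381 without mares 1, 3 and 5. List tests passing were 4 without mare 2 and 0 without mare 4 (camera, 14 of 102 at an unadjusted p under 0.05). The matrix list lay between −1.25 and −0.87, at −1.24 (adjusted p = 0.0798) without mare 4, and the secretory list between −1.90 and −1.18, at −1.47 (adjusted p = 0.125) without mare 4.

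Of 4104 values of named genes under these alternatives, 3156 kept direction and call, 941 lost the call and 7 reversed. Reversed were RPLP2 between days 0 and 16 with quantile normalization (−0.034), LGB1 between days 3 and 0 with the 3 normexp variants (−0.029, −0.054 with backgrounds replaced and −0.029 with those of 1 array), and, with the planned normexp, COX10 between days 8 and 3 (0.15), BDNF between days 12 and 8 (−0.63) and CXCL8 between days 8 and 0 (0.015). Calls were lost by 136 of 171 under some alternative, 111 with the planned normexp, 18 with marked backgrounds replaced and 16 with those of 1 array, 20 with quantile normalization, 24 with slide, 53 with the signal covariate, 58 on leaving out some array and 94 on leaving out some mare. With mare and slide, 64 of 171 kept theirs. Lost were 27 of 33 for days 3 and 0, 10 of 27 for days 8 and 3 and 12 of 12 for days 12 and 8. For days 16 and 12, days 0 and 16 and days 8 and 0, they were 9 of 30, 23 of 26 and 26 of 43.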

Other observations

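The tests of leukocyte markers and scaling for the chemokine and protease genes were chosen after the results were seen. PGRMC1, a membrane-associated progesterone receptor component, rose by 0.83 ± 0.23 from day 3 to day 8 and was higher at day 8 than at day 0 by 1.30 ± 0.23. RARB, a retinoic acid receptor, fell by 1.01 ± 0.22 from day 0 to day 3 in 4 of 5 mares. TAGLN, the tested marker of smooth muscle, rose by 1.46 ± 0.32 from day 12 to day 16. These genes were chosen after their values were seen.

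MMP3, CXCL8, CXCL9, CXCL10, MMP9 and CXCL6 were lower at day 8 than at day 0, with a median log2 change of −2.82, or −2.45 with those at background at their bounds. For T cells, NK cells, macrophages and dendritic cells, 9 markers had a median of −0.61 (SD 0.53), and 1 of them, CCL5, fell. Adjusted over their lists alone, 1 of 4 T and NK cell markers and 3 of 5 of macrophages and dendritic cells fell. The 6 genes were picked because they fell, and the markers were not, so the gap between their medians is partly built in. The markers show no loss of these cells as large as the median fall of the 6 genes, which leaves a smaller loss open. Scaling of the arrays is argued against by a median of −2.79 for the same 6 genes with quantile normalization. The size of their changes depends on the background correction and its offset, with a median of −1.75 and 5 of 6 called with marked backgrounds replaced. The median was −1.06 and 0 were called with the planned normexp, which broke down on 1 array of day 8. Fewer neutrophils cannot be told apart from lower expression, since 0 neutrophil markers outside these genes were tested. A hormone effect on expression within cells stays open and untested.

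Other assignments of the same arrays were drawn to see whether chance can be excluded. Of 100 assignments of the 25 arrays to days, drawn without regard to the mares, 1, the real one, gave as many as 12790 probes (highest other 993). Chance can be excluded under such assignments. The real one alone (1) gave as many as 802 opposite calls (highest other 1), but assignments that call few probes can share few, so this adds nothing on the overlap beyond the counts of calls. The 100 splits per comparison also ignored the mares. The real split alone (1) called as many for day 3 against day 0 (4533, highest other 2926), day 8 against day 3 (4927, 2697) and day 12 against day 8 (392, 1). The same held for day 16 against day 12 (2888, 833) and day 8 against day 0 (7837, 32). Chance can be excluded there under splits that ignore the mares. For day 0 against day 16, 3 of 100 splits called at least 1683, the highest other 2831. Among the 16 splits that part the arrays of each mare, 2 called as many for day 0 against day 16, so chance is left open for this comparison. For each other comparison 1 of the 16, the real one, did. With 16 such splits that is the smallest share possible, so they cannot exclude chance for any comparison. For the extracellular matrix list 5 of 100 splits gave a camera p as small as 8.89e-05 (smallest other 4.25e-05, permutation of arrays), and for the secretory list 5 gave one as small as 0.000208 (smallest other 4.28e-06), so chance cannot be excluded for either list. Of the splits that part the arrays of each mare, the highest other counts were 2926 for day 3 against day 0, with the arrays of mare 4 exchanged, and 1824 for day 0 against day 16, with those of mare 1 exchanged. In mare 4, the day 3 array lay nearer the day 0 end of the line (0.93) than its day 0 array did (0.86).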
